A study of Caenorhabditis elegans with 4 samples.

How the data were processed

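Single motor neurons of young adult wild-type C. elegans were measured by 10x Genomics droplet sequencing of the 3' ends of transcripts. Animals of 2 reporter strains were dissociated and fluorescent cells were sorted, with 2 libraries per strain. The acr-2::GFP strain carries juIs14, which also holds lin-15(+), and the lin-39p::RFP strain carries kasIs2, which also holds pha-1(+). Per the labels, the acr-2::GFP animals were digested with pronase at 15 mg/mL for 23 min at room temperature. The lin-39p::RFP animals were digested with a cold-active protease at 10 mg/mL for 35 min at 4 C. The lin-39p::RFP animals were also synchronised by mesh in addition to arrest as starved first-stage larvae. Per the labels, the authors ran Cell Ranger 6.0.2 on the acr-2::GFP libraries and Cell Ranger 6.1.1 on the lin-39p::RFP libraries. Strain, protease, synchronisation and software version therefore change together.

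The deposited matrices hold UMI counts, that is, unnormalised counts of transcript molecules per gene and cell barcode, for all cells and for ventral cord motor neurons alone. The authors' barcode tables, as deposited, give the library, the class and subclass, the total UMI counts and other values per barcode, such as genes per barcode and percentages. As deposited, they also hold a p-value per barcode and a score per barcode, a scaling factor of the authors that follows total UMIs. How the authors made these p-values and scores is not given in the sources used here, and neither was used. The annotation is the authors' own and was used without change, and how it was made is not given in the sources used here. If it rests on expression in these same cells, the genes used for it differ between the annotated groups by construction. The table of all cells holds 26686 barcodes and 15000 genes, and the motor neuron table holds 13200 barcodes and 10695 genes, with 0 entries that differ between the tables where both give a value. The table of all cells annotates 13202 barcodes as these motor neurons. Over all barcodes, UMIs in the matrices add up to 99.9% of the per-barcode totals. The lowest share in a single barcode was 42.9% in the table of all cells and 92.9% in the motor neuron table. Barcodes that hold more than 1 cell were not looked for, and free RNA was not subtracted. All 15005 gene identifiers of the tables were found in the deposited gene models, which follow WormBase release WS273 with 3' ends extended by the authors. Coordinates are from these models.

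UMI counts were summed per library and cell group, since the library, not the cell, is the replicate. Groups of cells with at least 20 cells in a library entered a comparison, or 10 cells for subclasses. The sums were tested with the quasi-likelihood F test of edgeR 4.0.16, after TMM scaling and the default filter on low counts, with a prior count of 0.125. A library term was fitted wherever both groups came from the same library. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called different at an adjusted p below 0.05 and a log2 difference of at least 1 in size. Standard errors were taken as the log2 difference divided by the square root of F. P-values measure only the spread between libraries, which was partly borrowed from other genes. For comparisons of cell groups, a gene was counted in the libraries that held both groups. Cholinergic and GABAergic neurons and VD and DD were compared in the 2 lin-39p::RFP libraries, and VA and DA in the 2 acr-2::GFP libraries, each with 1 residual degree of freedom. The spread fitted over all genes entered these tests with 10.93 prior degrees of freedom for transmitter and 7.295 for VD and DD. For VA and DA these were infinite, so the own spread of each gene had no weight. A-type (DA and VA) and B-type (DB and VB) neurons, VB and DB, and motor neurons and all other annotated cells were compared in 4 libraries. A single fit of 22 class sums, with 11 residual degrees of freedom, gave an F test over the 8 classes and the contrast of each class with the unweighted mean of the others. In that fit VA came only from acr-2::GFP libraries and AS, VC, DD and VD only from lin-39p::RFP libraries, so only DA, DB and VB linked the strains. The strains were compared within DA, DB and VB, without a library term. The difference of a contrast between the strains was tested with an interaction term, also for DA against DB, which was added after the data were seen. Genes were counted there by adjusted p alone, without the minimum fold, unless stated. The fits were also run on simulated counts with 100 genes changed 4-fold and 100 genes changed 2-fold, under a spread that was assumed and not taken from these libraries. The comparisons of groups recovered 79 to 97% of the former and 25 to 49% of the latter, with 0 to 11 false calls.

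The gene lists, comparisons, tests, thresholds, naming rule and most alternative settings were fixed before the data were examined. Lists were tested with camera from limma 3.58.1 with a preset correlation of 0.01. No list in any comparison kept an adjusted p below 0.05 with a correlation estimated from these sums. The lowest such adjusted p were 0.734 for transmitter, 0.731 for A and B types, 0.915 for VA and DA, 0.538 for VB and DB, 0.875 for VD and DD, 0.368 for motor neurons and other cells, and 0.645 for the strains in DA. For each of 20 gene families the share of genes that differed among classes was compared with 1000 lists matched on mean expression, drawn from the 100 nearest genes. Class assignment used 53 homeobox genes. Cells of a held-out library were assigned to the class of the other libraries with the highest Pearson correlation of log counts per 10000 UMIs. The result was compared with 100 matched lists.

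The rule for named genes takes the 12 genes with the largest log2 difference in each direction among those called, with a gene name, at least 50 CPM (counts relative to the total of the sum, after TMM scaling) in the higher group and the same direction in every library. It adds 3 such genes per class and per subclass, the genes of short fixed lists, and up to 4 called members per family. Genes in the text are a selection from these, and any gene outside the rule is said to be chosen after its values were seen. Where a group had 0 counts, the fold is given as a lower bound from 3 counts over the group. With 1 to 3 counts, the ratio of counts has a 95% interval. Shares of cells have 95% Wilson intervals, and a share of 0 allows up to 3 cells. Intervals and floors cover counting error only.

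The alternative settings fixed at that point were DESeq2 size factors, the Wald or likelihood ratio test of DESeq2 1.42.0, no filter on low counts, no library term (or, for the strains, the replicate number as a block), no minimum fold change, at least 50 cells per sum (20 for subclasses), all classes in 1 fit, cells thinned to 500 UMIs, genes linked to the transgenes left out, and each library left out. For shares they were all cells of the library as the denominator and cells with at least 1000 UMIs. For class assignment they were the same UMI minimum, no log transform, Spearman correlation, and nuclear hormone receptor genes. Further alternatives were chosen after the data were seen. These are the strains compared in the DA2_5 subclass alone, motor neurons against other neurons alone or non-neuronal cells alone, and, where 1 pair of libraries would leave no residual degrees of freedom, a library left out within the fit of all classes. Values were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3, and figures were drawn with matplotlib 3.10.9. Sequence reads were not used here.

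The motor neurons of the 4 libraries held 2551817 and 2647286 UMIs for acr-2::GFP and 7141562 and 6384658 UMIs for lin-39p::RFP. Between replicate libraries the spread of counts was 1.59 to 8.35 times that of sampling alone, so the replicates are not copies of one another.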

Results

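The 4 libraries hold 26686 annotated or unannotated cells, of which 13200 are ventral cord motor neurons of 8 classes and 29 subclasses. Motor neurons made up 43.9 and 42% of the cells in the acr-2::GFP libraries and 49.6 and 57.96% in the lin-39p::RFP libraries. The median motor neuron held 1177 and 1319 UMIs in acr-2::GFP and 1295 and 1378 UMIs in lin-39p::RFP, with 553, 625, 602 and 629 genes. Other neurons were 21.2 and 21.1% of cells in acr-2::GFP and 9.398 and 9.71% in lin-39p::RFP, and non-neuronal cells were 15.9 and 16.38% against 36.6 and 28.1%. Cells without an annotation were 19.01 and 20.5% against 4.43 and 4.26%. In motor neurons the authors' median percentage of stress genes was 5.12 and 4.78 in acr-2::GFP and 2.52 and 2.18 in lin-39p::RFP, and that of mitochondrial transcripts was 1.10 and 1.14 against 0.310 and 0.287. Below, differences are log2 values ± standard error, and expression is the mean in CPM ± standard deviation over libraries.

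The acr-2::GFP strain gave mostly the A and B types, and the lin-39p::RFP strain gave mostly AS, VC, VD and DD. Of the motor neurons of each acr-2::GFP library (n = 2), 34.7 ± 0.037% were VB, 25.2 ± 0.018% VA, 22.3 ± 0.109% DA and 16.9 ± 0.351% DB. In lin-39p::RFP (n = 2) these shares were 0.838 ± 0.412, 0.203 ± 0.086, 5.65 ± 1.06 and 1.91 ± 0.09%. The lin-39p::RFP libraries held 41.4 ± 4.15% VD, 25.5 ± 5.90% AS, 19.9 ± 1.98% VC and 4.61 ± 0.244% DD, against 0.340, 0.518, 0.026 and 0.049% in acr-2::GFP. Among 2126 motor neurons of the first acr-2::GFP library 0 were VC, which allows up to 0.141%. With 2 against 2 libraries the exact permutation p is 0.333 for each class, the smallest value possible. As a share of all cells the difference in DA was 6.58 in place of 16.7 percentage points, and the difference was smaller in every other class too.

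**Figure D1:**
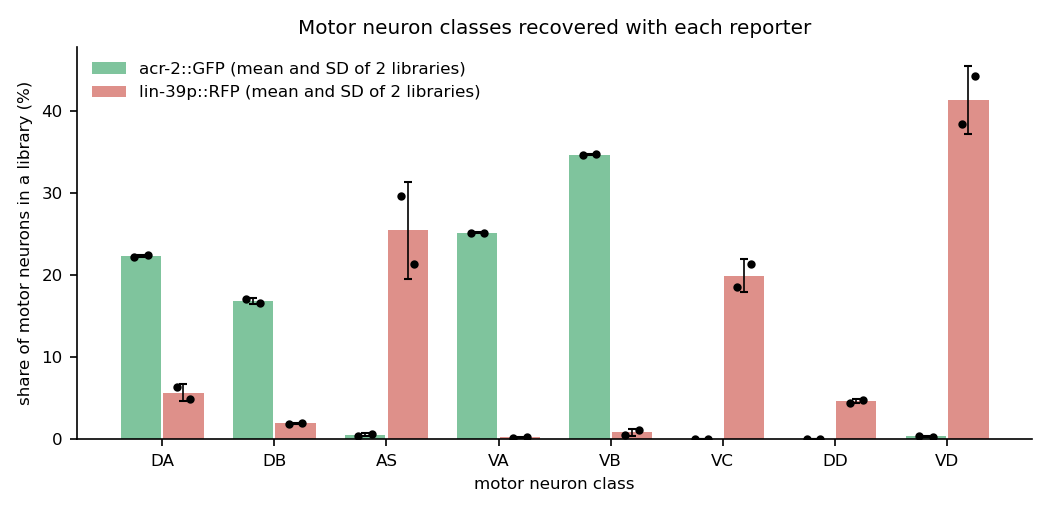
Share of each class among the ventral cord motor neurons of each strain, as mean and standard deviation of 2 libraries, with a point per library.

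GABAergic and cholinergic neurons differed in the genes that make and load their transmitters. In GABAergic cells unc-25, glutamate decarboxylase (WBGene00006762, III 12942333-12949947, WS273), was higher by 10.36 ± 0.23 (99200 ± 5349 against 76.1 ± 17.1 CPM, n = 2 lin-39p::RFP libraries). The vesicular GABA transporter unc-47 (8.28 ± 0.25), its sorting factor unc-46 (8.44) and the homeobox gene unc-30, which sets GABAergic fate (8.67 ± 0.21, 2713 against 6.58 CPM; WBGene00006766, IV 13119090-13124390), went the same way. Cholinergic cells were higher in the vesicular acetylcholine transporter unc-17, whose exons overlap cha-1 (-8.52 ± 0.23, 3.02 against 1118 ± 67.0 CPM; WBGene00006756, IV 3618259-3624703), in the choline transporter cho-1 (-7.52) and in unc-3, the terminal selector of cholinergic fate (-7.45 ± 0.27; WBGene00006743, X 14773538-14783564). Peptide genes differed as much. Higher in the cholinergic sums were nlp-6 (-10.56 ± 0.52, 35660 ± 2411 CPM), flp-28 (-10.18 ± 0.62, 45510 ± 5943 CPM), nlp-63 (-10.45) and flp-27 (-10.22), and higher in GABAergic cells flp-15 (9.36 ± 0.21, 5319 ± 346 CPM) and nlp-78 (9.23). The cholinergic cells of these libraries are mostly AS and VC, and these 4 cholinergic peptide genes are highest in VC: nlp-6 was at 80380 CPM in VC and 1085 in the next class, flp-28 at 102300 and 1253, nlp-63 at 7166 and 95.96, and flp-27 at 4027 and 24.88. Also GABAergic were the transthyretin-like gene ttr-39 (9.93), the homeobox genes alr-1 (9.57 ± 0.25) and dve-1 (8.91), the nicotinic receptor subunit unc-29 (8.24 ± 0.26), the sodium channel subunit deg-1 (6.74), the tyramine receptor ser-2 (5.90), the nuclear receptor unc-55 (3.04 ± 0.14) and the Hox gene ceh-13 (2.59 ± 0.15). With 0 counts in GABAergic cells, the zinc finger gene egl-46 (WBGene00001210, V 6679101-6681573) was higher in cholinergic cells by at least 659-fold (295 ± 15.8 CPM) and the potassium channel twk-18 by at least 79.7-fold. The gene egl-46 was also highest in VC (668 CPM, 17.6 in the next class). The Hox genes lin-39 (-0.89) and mab-5 (-0.99) did not pass the minimum fold.

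Of 7302 genes tested, edgeR called 2321, of which 968 were higher in GABAergic and 1353 in cholinergic cells. The cholinergic sums hold mostly AS and VC cells, and VC cells weigh more in them, with a median of 2399 UMIs against 868 in AS. These counts and the lists below thus compare mostly AS and VC with DD and VD, and are not shown for every cholinergic class. All 6 GABAergic identity genes were higher in GABAergic cells (camera adjusted p = 9.6e-05) and all 6 cholinergic identity genes lower (adjusted p = 0.000383), but every list was at an adjusted p of 0.734 or more with an estimated correlation. The authors' annotation may rest on these identity genes, so both list results describe the annotation. FLP peptide genes were 4 higher and 15 lower of 20 (adjusted p = 0.0102), NLP peptide genes 5 and 25 of 43 (adjusted p = 0.00403), potassium channels 8 and 22 of 38 (adjusted p = 0.0359) and nuclear hormone receptors 18 and 7 of 56 (19 and 7 adjusted over the list alone; adjusted p = 0.000928). Of 29 acetylcholine receptor and related channel genes 13 were higher and 13 lower, with a median of 0.27 and a mean of -0.51. Stress genes moved with the groups: 9 of 15 heat shock genes were higher in GABAergic cells and 0 lower (adjusted p = 0.00241, or 0.734 with an estimated correlation), among them hsp-16.11 (2.85 ± 0.30, 1849 ± 550 against 331 ± 315 CPM). The muscle myosin gene unc-54 was lower in GABAergic cells (-1.54 ± 0.15, 12470 against 36330 CPM). With all classes in 1 fit the calls for ttr-39, flp-28, nlp-63, flp-27, alr-1, egl-46, unc-29 and unc-54 ended and the count was 1435. With each library left out in that fit the count was 1270 or 1282. The larger direction turned in these 3 settings, with 737 genes higher in GABAergic and 698 in cholinergic cells with all classes, and 718 and 552 or 686 and 596 with a library left out. With all libraries that fit left 261 of 6317 transmitter contrasts open, with an F test p above 0.9 beside a log2 difference above 2 in size. Of these 64 were higher in GABAergic cells, and 51 were called without the library term. Open contrasts count as not called, so an ended call need not mean a small difference. The gene ttr-39 was at 16270 CPM in DD, 26100 in VD and at most 35.84 in a cholinergic class.

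A-type and B-type neurons differed in transcription factor and peptide genes. The homeobox gene unc-4, which keeps B-type programs off in A-type cells (WBGene00006744, II 9897751-9900376), was higher in A by 6.06 ± 0.22 (1668 ± 291 against 25.7 ± 13.03 CPM, n = 4 libraries). In B the homeobox genes ceh-12 (-7.30 ± 0.30; WBGene00000436, I 5840282-5841940) and vab-7 (-7.14 ± 0.41; WBGene00006873, III 10920336-10926508) and the bHLH genes hlh-17 (-9.25 ± 0.27, 1715 ± 496 CPM) and hlh-32 (-8.54 ± 0.42) were higher. A-type cells held more nlp-13 peptide transcript (5.72 ± 0.22, 5177 ± 788 CPM; WBGene00003751, V 4236418-4238056) and nlp-11 (5.09 ± 0.63). B-type cells held more of the locomotor peptide gene pdf-1 (-6.50 ± 0.35), flp-9 (-5.80 ± 0.41, 26900 ± 5451 CPM), flp-18 (-4.31 ± 0.76; WBGene00001461, X 3012182-3018555) and flp-11 (-2.70 ± 0.23). The peptide receptor genes frpr-5 (6.13) and dmsr-2 (-6.87 ± 0.29) went in opposite directions. Also higher in A were the acetylcholine receptor genes acr-14 (4.15 ± 0.30) and acr-19 (3.09), the potassium channel twk-40 (2.18 ± 0.16), and the Hox genes ceh-13 (2.90 ± 0.19) and mab-5 (1.76 ± 0.18). The semaphorin gene smp-1 had a ratio of 203 (69.2 to 989) over 3 counts in B, and the immunoglobulin genes rig-4 and igcm-1 ratios of 174 (30.8 to 6916) and 109 (29.8 to 907). The GABAergic gene unc-25 was also higher in A (2.03 ± 0.44, 72.4 against 20.2 CPM), in 3 of 4 libraries. A few cells held most of its UMIs, with 24 of 30 in 1 VA cell of the acr-2::GFP libraries and 65.79% in cells with 10 or more among DA cells of the lin-39p::RFP libraries.

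Of 4960 genes tested, 450 were called, 200 higher in A and 250 higher in B. Of 7 FLP peptide genes 0 were higher and 5 lower in A (7 lower adjusted over the list alone; camera adjusted p = 0.000468), and of 3 Hox genes 2 were higher (adjusted p = 0.0136), but every list was at an adjusted p of 0.731 or more with an estimated correlation. The bHLH genes were 0 higher and 2 lower of 10 (adjusted p = 0.0421). NLP peptide genes were 3 higher and 8 lower of 19 (3 and 10 adjusted over the list alone), and neuropeptide receptors 10 and 9 of 35 (11 and 9 alone). By adjusted p alone, the A to B difference itself differed between the strains for 301 genes (191 with the minimum fold), among them nlp-11 (by 3.56), flp-9 (2.02), flp-18 (4.25) and flp-11 (1.19). The groups hold different classes, since A was 316 DA and 7 VA cells in the first lin-39p::RFP library and 473 DA and 535 VA cells in the first acr-2::GFP library, and B was mostly DB in the former and mostly VB in the latter. For DA against DB alone, whose subclasses also differ between the sorts, the number was 142 by adjusted p alone (90 with the minimum fold). The count was 298 without the first acr-2::GFP library, 222 without the library term, 725 with all classes in 1 fit and 854 without the filter. Without the library term the calls for flp-18, mab-5 and unc-25 ended.

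Ventral and dorsal A-type neurons differed in bnc-1 and unc-129. The zinc finger gene bnc-1 (WBGene00044791, V 12275570-12277046) was higher in VA by 6.34 ± 0.14 (2246 ± 5.88 against 27.4 CPM, n = 2 acr-2::GFP libraries). The TGF-beta ligand unc-129, which guides axons to the dorsal cord (WBGene00006852, IV 9002837-9005410), was higher in DA (-6.66 ± 0.16, 18.5 against 1910 ± 6.68 CPM). VA also held more of the peptide genes nlp-58 (6.36 ± 0.11; WBGene00077775, V 9946321-9948940), flp-32 (6.57 ± 0.25), flp-20 (6.05) and flp-18 (2.32 ± 0.08), the sodium channel subunits asic-1 (5.62 ± 0.27) and del-1 (4.99 ± 0.30), and the immunoglobulin gene oig-1 (4.18 ± 0.50; WBGene00003859, III 6524051-6525660). Over 1 to 3 counts in DA, the netrin gene unc-6 had a ratio of 95.2 (32.3 to 465), the ligand-gated channel lgc-36 of 217 (73.99 to 1056), the glutamate receptor mgl-3 of 59.3 (20.0 to 290) and ham-1, a regulator of asymmetric division, of 80.2 (21.8 to 668). DA held more of the T-box gene mab-9 (-5.14 ± 0.26), the GABA-B receptor gbb-2 (-6.18 ± 0.29), the nicotinic subunit lev-1 (-5.20) and the netrin receptor unc-5 (-2.45 ± 0.25), and acr-17 had 0 counts in VA, at least 40.5-fold. The shared regulators unc-4 (0.19) and unc-3 (0.64) did not pass the minimum fold. Of 4611 genes tested, 488 were called, 277 higher in VA and 211 higher in DA. FLP peptide genes were 7 higher and 0 lower of 10 (camera adjusted p = 4.7e-05, or 0.915 or more with an estimated correlation), collagens 7 and 0 of 22 (8 and 0 adjusted over the list alone; adjusted p = 0.00477) and acetylcholine receptor genes 3 and 6 of 20 (adjusted p = 0.0186). DEG/ENaC channels were 2 higher and 2 lower of 5, with a median of -0.91 and a mean of 0.72. The count was 189 with the DESeq2 Wald test, which ended the call for acr-17. It was 444 with all classes in 1 fit, and 270 or 258 with a library left out in that fit.

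Ventral and dorsal B-type neurons also differed in bnc-1 and unc-129. In VB the homeobox gene ceh-12, a brake on A-type traits, was higher by 7.68 ± 0.32 (1316 ± 133 against 4.00 CPM, n = 4 libraries) and bnc-1 by 5.82 ± 0.37. In DB the homeobox gene vab-7, which sets DB axon direction (-7.13 ± 0.28, 20.0 against 1394 ± 603 CPM), unc-129 (-6.44 ± 0.22), pdf-1 (-6.33 ± 0.18, 3930 ± 897 CPM), msa-1 (-5.86 ± 0.21), mab-9 (-5.57 ± 0.27) and gbb-2 (-4.78 ± 0.32) were higher. The subunit lev-1 was higher in DB with a ratio of 39.3 (13.02 to 194). VB held more nlp-58 (5.48 ± 0.22), nlp-45 (7.15 ± 0.31), flp-32 (6.26 ± 0.34), flp-16 (2.71 ± 0.16), unc-6 (5.97 ± 0.42), lgc-36 (6.16), asic-1 (5.32), mgl-3 (4.18), oig-1 (5.52 ± 0.46) and del-1 (2.34 ± 0.29). The muscle myosin gene unc-54 was lower in VB (-1.20 ± 0.32, 28530 against 44630 CPM). Of 3379 genes tested, 378 were called, 171 higher in VB and 207 higher in DB. The VB sums held only 27 and 47 cells in the lin-39p::RFP libraries, against 737 and 685 in acr-2::GFP. NLP peptide genes were 9 higher and 1 lower of 16 and acetylcholine receptor genes 0 and 6 of 19, each at a camera adjusted p of 0.00439, or 0.538 or more with an estimated correlation. The 14 heat shock genes had 0 higher and 3 lower, with a median of 0.23 and a mean of -0.11. The difference itself differed between the strains for 89 genes by adjusted p alone (61 with the minimum fold). The count was 186 or 175 without an acr-2::GFP library, 176 without the library term, 690 with at least 50 cells per sum and 610 with all classes in 1 fit. The call for unc-54 ended with the DESeq2 Wald test, without the library term, with at least 50 cells per sum, without the second acr-2::GFP library and without the first lin-39p::RFP library.

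Among GABAergic neurons, DD and VD differed in peptides, channels and the regulators irx-1 and unc-55. In DD the peptide gene flp-14 (-9.61 ± 0.11, 12.57 against 9877 ± 1611 CPM; WBGene00001457, III 12910467-12914930; n = 2 lin-39p::RFP libraries), the homeobox gene irx-1, which drives DD rewiring (-8.40 ± 0.26; WBGene00007984, I 9536465-9540966), the peptide gene flp-13 (-4.20 ± 0.16) and the lipid-binding gene far-1 (-7.66 ± 0.34) were higher. The channel subunits del-1 (-7.53 ± 0.31), del-8 (-2.75 ± 0.16) and unc-8 (-2.76 ± 0.30), the adhesion gene syg-1 (-3.01) and the cadherin cdh-4 (-2.98) were also higher in DD. VD held more unc-55, the nuclear receptor that blocks rewiring in VD (3.71 ± 0.18, 624 ± 22.6 against 47.4 CPM; WBGene00006790, I 7898434-7903334), and oig-1, which holds synapses in place (4.49 ± 0.14, 3511 ± 353 CPM). Also higher in VD were flp-9 (2.71 ± 0.13), flp-11 (2.13), lntl-1 (4.95 ± 0.14), whose exons overlap noncoding RNAs, str-155 (4.84), acr-9 (1.63) and mab-9 (1.12 ± 0.11). The shared genes unc-25 (0.31) and unc-30 (0.34) did not pass the minimum fold. The tropomyosin lev-11 (4.38 ± 0.25, 315 ± 92.0 against 15.0 CPM) and 6 of 15 heat shock genes were higher in VD (camera adjusted p = 0.0266, or 0.875 with an estimated correlation), including F44E5.4 (2.41 ± 0.29) and hsp-16.11 (2.37 ± 0.40). Of 5456 genes tested, 541 were called, 250 higher in VD and 291 higher in DD. DEG/ENaC channels were 0 higher and 3 lower of 5 (adjusted p = 0.00362, or 0.875 or more with an estimated correlation), and FLP peptide genes 4 and 3 of 8, with a median of 1.16 and a mean of -0.88. The count was 280 with the DESeq2 Wald test. With all classes in 1 fit it was 527, with 272 higher in VD and 255 in DD, and in that fit it was 396 without the first lin-39p::RFP library and 337 without the second.

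Regulators of cell fate differed in level among the classes. The homeobox gene unc-4 was at 1532 ± 219 CPM in DA, 1946 ± 163 in VA and 3060 ± 2.53 in VC, and vab-7 at 1302 ± 561 in DB and 949 ± 6.00 in VC. In VB ceh-12 reached 1171 ± 72.6 CPM, with 6.98 in the next class (10.53 ± 0.28 above the mean of the others), and bnc-1 2152 ± 5.90 in VA and 1195 ± 127 in VB. The LIM homeobox gene lin-11 (981 ± 131 CPM; WBGene00003000, I 10248227-10255327) marked VC, where unc-3 was at 7.43 CPM, against 503 in AS, 432 in VA, 303 in DA, 253 in VB and 203 in DB. In DD irx-1 was at 409 ± 30.2 CPM, with 1.20 in the next class. The GATA factor elt-1 was at 487 ± 61.8 CPM in AS, 266 in VD and 179 in DD, and unc-55 at 738 ± 14.5 in VD and 284 ± 48.1 in AS. Among effector genes, pdf-1 was highest in DB (9.55 ± 0.22), the neuropeptide receptor npr-2 in AS (6.81, 2845 ± 195 CPM), the secreted Wnt inhibitor sfrp-1 in VA (769 ± 78.3 CPM, 105.2 in the next class), nlp-63 in VC (10.80, 7166 ± 582 CPM) and oig-1 in VD (4153 ± 349 CPM). Of 6317 genes tested 4349 differed among classes. Against the mean of the others 652 genes were raised in DA, 650 in DB, 634 in AS, 631 in VA, 701 in VB, 1074 in VC, 630 in DD and 771 in VD. For 3.31 to 6.22% of genes per class the fit leaves the contrast open, and these were counted as not raised. Of the open genes 204 of 227 in VB but 94 of 393 in VD had at most 3 counts, within a strain, in the classes found in both strains.

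**Figure D2:**
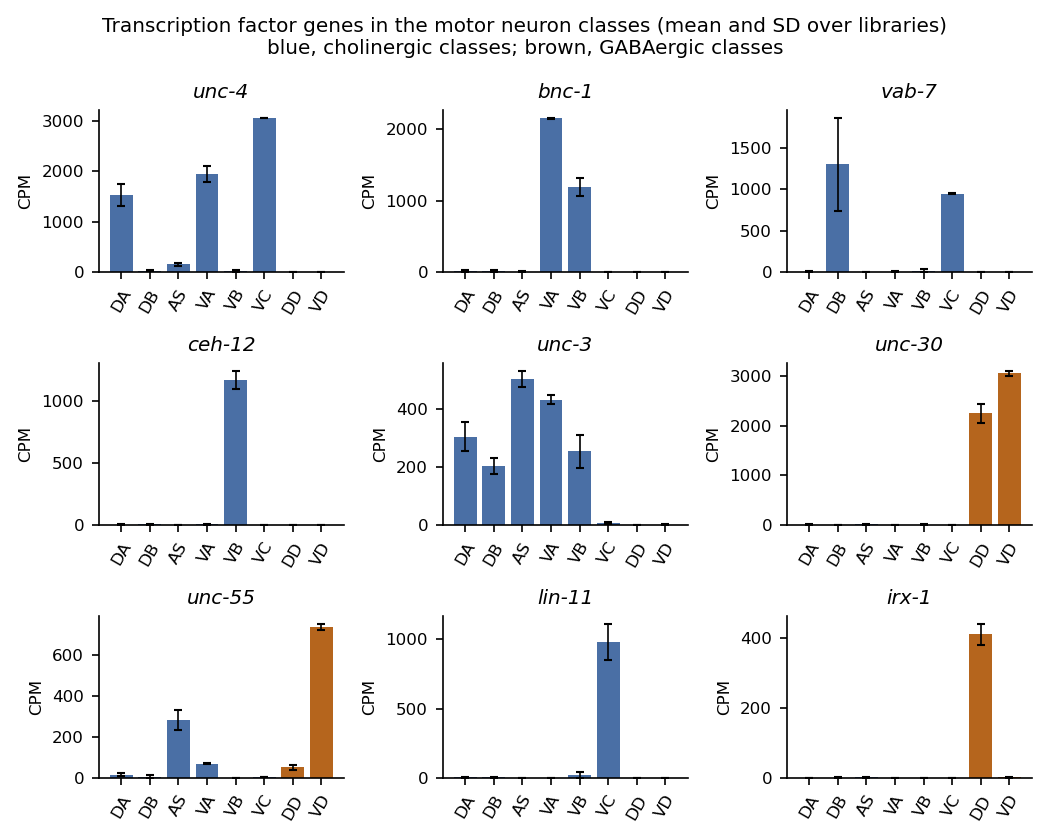
Mean expression and standard deviation over libraries of 9 transcription factor genes by class, with cholinergic classes in blue and GABAergic classes in brown.

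Some gene families differed among classes more often than genes of the same expression, and others did not. Of 63 neuropeptide receptor genes 62 differed (98.4%; median of matched lists 69.8%; 0 of 1000 matched lists as high; Fisher adjusted p = 5.8e-08). All 39 potassium channel genes, all 29 acetylcholine receptor and related genes, 46 of 47 immunoglobulin and leucine-rich repeat genes, 39 of 40 NLP peptide genes, 36 of 37 receptors gated by GABA, glutamate or amines, 33 of 36 collagens and 39 of 44 nuclear hormone receptors also had 0 of 1000 matched lists as high. FLP peptide genes were 22 of 22 (78 lists as high), synaptic vesicle genes 32 of 32 (138), homeobox genes 27 of 31 (189), ribosomal protein genes 76 of 80 (627), heat shock genes 13 of 16 (943) and bHLH genes 9 of 13 (838). DEG/ENaC channels were 6 of 6 (285), innexins 5 of 5 (325), insulin-like genes 4 of 4 (330), zinc finger genes 19 of 27 (550), mitochondrial genes 12 of 12 (570) and unfolded protein response genes 8 of 11 (808). Homeobox genes were called more often than all other genes (Fisher adjusted p = 0.048) but not clearly more than matched lists. Their median specificity was 0.689 against 0.501 (7 of 1000 lists as high). It was higher in DEG/ENaC channels (0.793 against 0.469; 7 lists), FLP peptide genes (0.964 against 0.5; 0 lists), NLP peptide genes (0.918 against 0.525; 0 lists) and neuropeptide receptors (0.818 against 0.503; 0 lists). Assigning the cells of a held-out library from 53 homeobox genes alone was right for 60.4 ± 11.1% of cells averaged over classes (n = 4), against a median of 35.8% and a range of 20.8 to 49.4% in 100 matched lists. By class and library it ranged from 9.09% for VA in the second lin-39p::RFP library (11 cells) to 95.6% for DB in the first lin-39p::RFP library. AS in the second acr-2::GFP library (13 cells) gave 23.1%, and DA in the first acr-2::GFP library gave 24.1%. Spearman correlation gave a similar mean of 57.7%, but classes moved in the lin-39p::RFP libraries. VD fell from 83.4 and 82.8% to 26.3 and 21.8%, and AS from 77.8 and 80.9% to 55.3 and 47.6%. DD rose from 54.3 and 56.3% to 79.0 and 82.4%, and VC from 86.9 and 83.0% to 94.5 and 91.9%. From 4 to 8 classes were tested per library, with 12.5% by chance. Nuclear hormone receptors gave 22.4%, with 83 of 100 matched lists as high. The authors' annotation may rest on these genes, so the assignment describes the annotation.

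**Figure D3:**
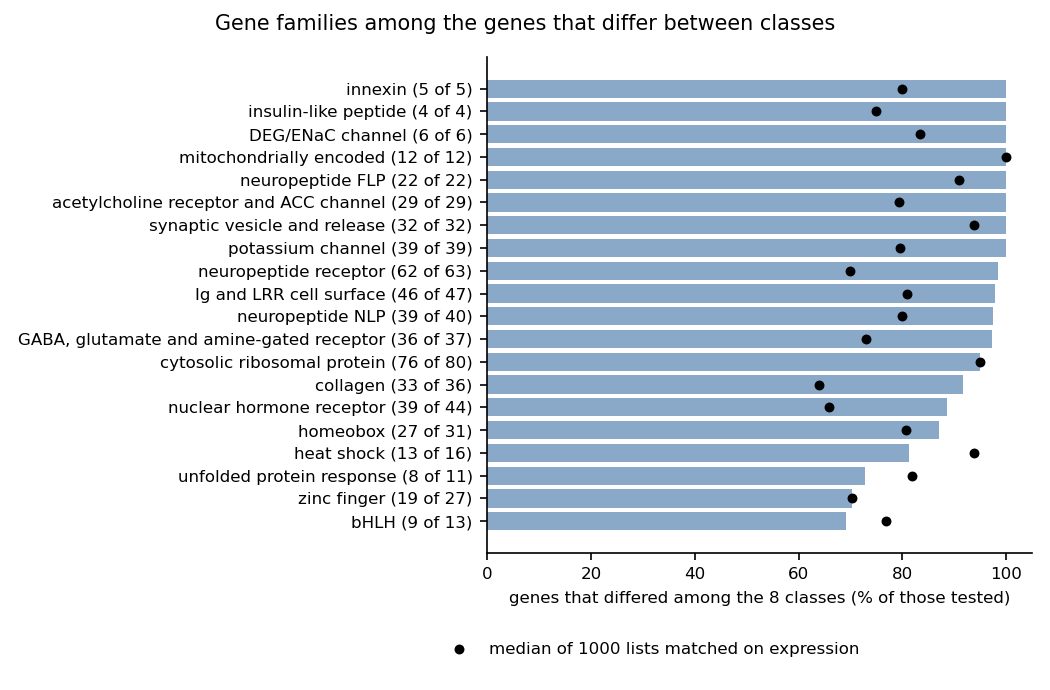
Percentage of tested genes that differed among the 8 classes for each gene family, with the median of 1000 lists matched on expression as a dot.

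Within classes, Hox genes differed between subclasses, whose neurons are numbered from front to back. The cells of AS, VC, DD and VD came almost only from the sort on lin-39p::RFP, a reporter named for a Hox gene. Their annotated subclasses start at AS2_3, DD2_3 and VD3_7, so the ends of these classes may be missing from the patterns below. The posterior gene egl-5 (WBGene00001174, III 7814374-7817140) was tested only in the last members DA9 (311 ± 161 CPM, n = 2) and VA12 (206 ± 53.5 CPM). A gene not tested in a subclass is not shown to be absent from it. The gene mab-5 (WBGene00003102, III 7776835-7783454) was raised in high-numbered subclasses such as AS11 (1747 ± 398 CPM), VA11 (832 ± 57.7), VB10_11 (794 ± 108), DA6_8 (583 ± 98.96) and VD12 (511), but was lower in VA12 (18.7 CPM). Among VC neurons mab-5 was raised in VC4_5 (968 ± 19.3 CPM), which lies in front of the last VC neuron. The gene lin-39 (WBGene00003024, III 7528641-7536649) was raised in AS4_8 (1532 ± 41.5 CPM), VA3_8 (723) and DA2_5 (678), in DB3_7 (815), the hindmost DB subclass, and in VC1_3_6 (1167), which holds the first and last VC neurons. The gene ceh-13 was raised in AS2_3 (1037 ± 67.6 CPM), DA1 (518 ± 21.4) and VA2 (348), and also in VD3_7 (761). The peptide genes flp-12 (WBGene00001455, X 4591281-4592404) and flp-4 marked the tail neurons DA9 (94480 ± 2277 and 15590 CPM) and VA12 (80050 ± 8123 and 20470 ± 2499 CPM). The bHLH genes hlh-17 and hlh-32 marked DB2 (6015 and 2556 CPM) and VB2 (6571 ± 238 and 4453 CPM), and nlp-79 and nlp-50 marked VC4_5 (18900 ± 1512 and 15640 ± 385 CPM). The homeobox gene vab-3 was raised in AS11 (324 ± 204 CPM) and VD12 (419 ± 79.6 CPM), and npr-2 (1890 ± 48.3 CPM) and the insulin gene ins-17 (2253 ± 423 CPM) in DA1. The leading genes of VD8_11 were muscle genes, tnc-2 (160 ± 172 CPM), tni-4 (50.5 ± 56.0) and mlc-3 (312 ± 317), with most of their counts in 1 library. At least 10 genes were raised in 28 of 29 subclasses, with 578 in VC1_3_6 and 9 in VB3. This number was 16 or 17 with a library left out, since a subclass needs 2 libraries for a test. The authors' annotation of subclasses may rest on expression in these cells, so raised genes may follow from it by construction. VC and DD have 2 subclasses each, so within each of these classes the 2 results are 1 test read both ways. The 578 genes raised in VC1_3_6 are those lowered in VC4_5.

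**Figure D4:**
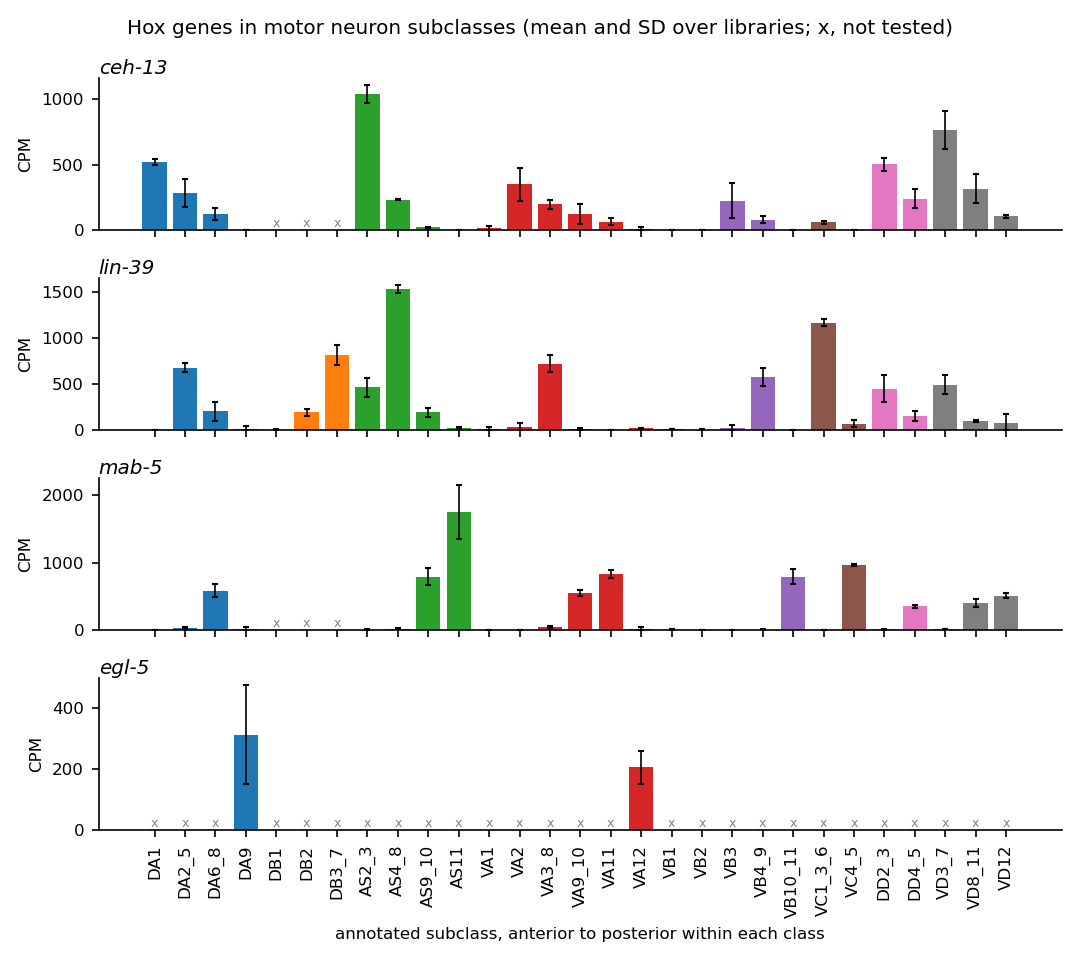
Expression of 4 Hox genes by subclass as mean and standard deviation over libraries, with a cross where a gene was not tested.

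Against all other annotated cells, motor neurons were higher in 9 of 15 class transcription factors and lower in 0 (10 higher adjusted over the list alone; camera adjusted p = 8.1e-05, or 0.368 or more with an estimated correlation), while homeobox genes as a whole were 17 higher and 16 lower of 52. The authors' annotation may rest on these class factors. The genes unc-4 (5.93 ± 0.37, 802 ± 116 against 13.5 CPM, n = 4 libraries), vab-7 (6.07 ± 0.45), tlp-1, a zinc finger gene of cell fate (5.10), and the synapse organiser madd-4 (5.14 ± 0.25) were higher. So were acr-9 (5.53 ± 0.21), acr-14 (4.39), the potassium channel twk-30 (5.17) and the release factor unc-18 (2.64 ± 0.41). The cholinergic genes unc-3 (3.50 ± 0.62) and unc-17 (3.38 ± 0.60) were higher too, but the calls ended against other neurons alone (2.44 and 2.10). The insulin genes ins-26 (-11.84 ± 0.53) and daf-28 (-10.79 ± 1.03) and the muscle gene cpn-3 (-10.24 ± 0.44) were lower. The muscle myosin gene unc-54 was higher in motor neurons (2.62 ± 0.26, 39120 ± 15320 against 6293 ± 2276 CPM; WBGene00006789, I 14855901-14863573), while 9 of 13 body wall muscle markers (10 adjusted over the list alone) were lower and 1 higher. Of 9330 genes tested, 3867 were called, 1315 higher and 2552 lower in motor neurons. Acetylcholine receptor genes were 17 higher and 0 lower of 28 (camera adjusted p = 3.2e-07, or 0.368 or more for every list with an estimated correlation), neuropeptide receptors 24 and 19 of 80, pan-neuronal genes 9 and 0 of 15, synaptic vesicle genes 18 and 3 of 34 (19 and 3 adjusted over the list alone), insulin-like genes 0 and 17 of 17, collagens 2 and 70 of 85 (2 and 72 alone) and ribosomal protein genes 0 and 75 of 80. Markers of other cells were lower, with 12 of 14 for germline (13 alone), 8 of 9 for cilia, 8 of 8 for sperm, 5 of 5 for intestine and 4 of 4 for pharynx. The difference itself differed between the strains for 3529 genes by adjusted p alone (2883 with the minimum fold). But the other cells were not the same, with AIZ, DVB and RIG neurons only in acr-2::GFP and AVM only in lin-39p::RFP. The 197 excretory gland cells were also only in acr-2::GFP, and at a median of 12289 UMIs they weigh heavily in its sums of other cells. Against other neurons alone the count was 1038, with 344 higher and 694 lower in motor neurons. Against non-neuronal cells alone it was 4917, with 2445 higher and 2472 lower.

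Within DA, some heat shock genes, some peptide genes and genes linked to the transgenes were among those that differed between the strains. In acr-2::GFP the small heat shock genes hsp-16.11 (4.22 ± 0.64, 5405 ± 1931 against 271 ± 338 CPM, n = 2 against 2 libraries; WBGene00002017, V 9090077-9090604) and hsp-16.48 (5.22 ± 0.44), the heat shock gene F44E5.4 (3.02 ± 0.44), the stress regulator xbp-1 (1.79 ± 0.15) and the immune regulator zip-2 (1.46 ± 0.17) were higher. The peptide genes flp-12 (9.71 ± 0.36, 4980 ± 679 against 4.70 CPM), flp-18 (3.91 ± 0.26) and nlp-11 (2.50 ± 0.16) were higher, flp-4 had 0 counts in lin-39p::RFP (at least 179-fold), and ins-17 had a ratio of 84.2 (14.9 to 3350). In DA2_5 alone the differences in flp-18 (-0.015) and nlp-11 (-0.13) were gone, and flp-12, flp-4 and ins-17 mark DA9 or DA1, of which the lin-39p::RFP libraries held 0 cells. The potassium channel twk-43 (3.04 ± 0.22) and unc-54 (1.98 ± 0.14, 72030 ± 3395 against 18300 ± 519 CPM) were higher in acr-2::GFP. The overlapping genes lin-15A (6.20 ± 0.25) and lin-15B (4.99 ± 0.20) were higher in acr-2::GFP, whose transgene holds lin-15(+), and pha-1 was lower (-6.83 ± 0.23). The lin-39p::RFP transgene holds pha-1(+), and whether counts of these genes come from the transgenes was not tested. In lin-39p::RFP the acyl-CoA synthetase acs-2 (-3.04 ± 0.21), the peptide receptor npr-3 (-2.01 ± 0.16), unc-129 (-1.21 ± 0.14), unc-18 (-1.04 ± 0.15), and, with 0 counts in acr-2::GFP, tts-2 (at least 123-fold) and unc-25 (at least 62.3-fold) were higher. The collagen col-81 had a ratio of 43.4 (11.4 to 368). Of 4308 genes tested, 724 were called, 371 higher in acr-2::GFP and 353 higher in lin-39p::RFP, with 716 in DB and 477 in VB. The VB sums of the lin-39p::RFP libraries held only 27 and 47 cells. Subclasses differ in DB and VB too, as acr-2::GFP held 241 DB1 and 407 VB2 cells and lin-39p::RFP 0 of each, and only DA was compared within a subclass. Heat shock genes were 8 higher and 0 lower of 14 (camera adjusted p = 0.150), FLP peptide genes 5 and 0 of 8 (camera adjusted p = 0.00309, or 0.645 or more with an estimated correlation) and collagens 1 and 9 of 22 (adjusted p = 0.0122). The count in DA was 412 with the DESeq2 Wald test (184 higher in acr-2::GFP and 228 in lin-39p::RFP) and 446 with thinned cells, in DB 183 without the filter and 451 or 418 without an acr-2::GFP library, and in VB 132 or 128 without an acr-2::GFP library and 261 without the second lin-39p::RFP library.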

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

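The tests of other splits, of depth on the genes still tested after thinning, and of flp-12 and flp-4 by subclass were chosen only after the results were seen, as was the control for thinning. The tests of unc-25 were chosen after its difference in DA was seen but before the counts per cell were. The criteria of the remaining tests were set before any of these results were computed.

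The muscle myosin gene unc-54 was counted at 39120 ± 15320 CPM in motor neurons, and it differed between strains, transmitter groups and VB and DB. The ratio of unc-54 to the muscle myosin myo-3 was at least 994 times that of body wall muscle cells in every library. It was 4889 times in the first acr-2::GFP library, over only 2 myo-3 UMIs, and at least 3604 times in the second, over 0. This argues against free RNA from muscle, which would carry both genes. Reads from reporter transcripts that end in the unc-54 3' UTR would give such a ratio (994), but the 3' UTRs of the transgenes are not given in the sources used here. No biological explanation was tested.

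The 724 genes that differed between the strains in DA have several candidate explanations, and strain, protease, synchronisation and software version cannot be told apart. A different mix of subclasses is argued against as the main cause for the 615 genes tested in DA2_5, whose median difference was 0.981 times that in all DA cells and of which 506 were called there. It does fit flp-12 and flp-4, with at least 99.66% of their UMIs in DA1 and DA9 cells, and the differences in flp-18 (-0.015) and nlp-11 (-0.13) are gone in DA2_5. Depth per cell stays open. Genes still tested after thinning kept 0.997 times the difference, but random thinning leaves the expected ratio of sums unchanged, so this cannot tell. Sums thinned without equalising cells gave medians of 1.395 to 1.463, around the 1.404 after equalising. The share of calls kept (48.34%) cannot tell either, as thinning alone kept 44.61 to 50.28% in 10 control draws. A cause shared by all cell types stays open. Of the genes tested there, 50.57% of 176 had the same sign in body wall muscle, 56.64% of 286 in germline and 80.14% of 141 in epidermis. Over all genes tested in both, these shares were 45.62, 51.87 and 57.8%. Of genes called in both, 27 of 51, 18 of 20 and 28 of 35 had the same sign. In the other motor neuron classes 95.8% of 547 genes in DB and 89.24% of 567 in VB had the same sign, though subclasses differ there too.

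The GABAergic gene unc-25 had 114 UMIs in 36 of 520 DA cells of the lin-39p::RFP libraries and 0 in 915 DA cells of the acr-2::GFP libraries. Free RNA would spread thinly over cells, and as only 30.7% of the UMIs lay in cells with 3 or fewer, it is argued against as the source of all of them. It stays open for that part. In AS of the same libraries 7.36% of cells held unc-25, against 6.92% of DA cells, with 69.82% of the UMIs in cells with 3 or fewer. In DB and VB 53.85 and 100% lay in such cells and 0% in cells with 10 or more. VC of the same libraries went the other way, and only 0.887% of 1803 VC cells held unc-25. There 87.39% of the UMIs lay in cells with 10 or more, with up to 99 in a cell. The VC values go against free RNA spread evenly over all cells. Barcodes that hold a DA cell and a GABAergic cell stay open for part of the UMIs in DA, as 65.79% of these lay in cells with 10 or more. But no DA cell held more than 23, while 3744 VD cells of the same libraries held 465905. The cut at 10 thus does not show that a whole GABAergic cell was present. Low expression of unc-25 in a few DA cells was not tested and stays open.

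Other splits of the 8 sums into equal groups were set beside the comparisons of 4 libraries. For motor neurons and other cells, 1 of 35 splits, the real one, gave 3867 genes and the highest other, the split by strain, gave 82. For A-type and B-type neurons 2 of 35 splits gave at least the real 450, and for VB and DB 2 of 35 gave at least the real 378. The larger counts, 787 and 491, came from the split by strain, which follows whole libraries and so was fitted without the library term. Among other splits that take the library term the highest counts were 2 and 17, against the blocked real values of 450 and 378. The count of 2 of 35 thus sets unlike fits side by side and by itself does not exclude a chance split. Among the 32 splits that take the library term 1, the real one, was as large in each comparison. Only 8 of the 32 part the groups in all 4 libraries as the real one does, with 0 genes as the highest other. As 8 are too few for a share under 0.05, a chance split is not excluded in any of these comparisons.

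By adjusted p alone, a test of the difference itself between the strains, acr-2::GFP minus lin-39p::RFP, singled out 301 genes for A-type and B-type neurons (191 with the minimum fold), 89 for VB and DB (61) and 3529 for motor neurons and other cells (2883). The groups do not hold the same classes, subclasses or cell types in each strain, so these are not strain effects on the same cells, and DA against DB alone gave 142 by adjusted p alone. For A minus B these include nlp-11 (3.56), flp-9 (2.02), flp-18 (4.25), flp-11 (1.19), twk-40 (-0.59) and unc-129 (0.60). For VB minus DB they include unc-54 (1.78) and bnc-1 (-7.06), the latter with 0 counts in DB of lin-39p::RFP, so its value depends on the prior count. For motor neurons minus other cells they include unc-4 (-1.02), unc-3 (2.04), unc-17 (2.20), madd-4 (-0.56) and unc-18 (-1.54). Cells without an annotation, which no comparison used, held unc-17 at 188, 112, 291 and 255 CPM and unc-25 at 721, 1306, 13988 and 15256 CPM in the acr-2::GFP and lin-39p::RFP libraries in turn, above the limits that 0 counts allow (at most 31.4 CPM). In non-neuronal cells unc-17 was at 3.53, 3.23, 7.82 and 3.28 CPM and unc-25 at 40.29, 28.68, 438.18 and 209.94 CPM. In motor neurons unc-17 was at 849, 821, 701 and 690 CPM and unc-25 at 239, 303, 38102 and 39983 CPM.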

How the results depend on the processing

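Of 239 alternatives for the counts, shares and accuracy, 181 stayed within 1.5 times the count, or within 1 standard deviation between libraries for shares and accuracy, and 58 moved further. The differences in class shares reversed their sign in 0 of them. Counts and accuracy have no sign to reverse. The larger direction did turn for some counts, as for transmitter with all classes in 1 fit (737 higher in GABAergic and 698 in cholinergic cells). That fit left 261 transmitter contrasts open, and these count as not called. Of 1364 for 150 named genes, 1311 kept the call, 46 lost it, 2 gained it and 5 reversed the sign. The cause was not tested unless stated. The reversed values are mab-5 between transmitter groups, itself not past the threshold, at 0.37 with all classes in 1 fit and 0.21 to 0.58 with a library left out, and flp-18 (-0.015) and nlp-11 (-0.13) between the strains in DA2_5 alone, an alternative chosen after the data were seen. No minimum fold change gave 3610 genes for transmitter, 834 for A and B, 966 for VA and DA, 672 for VB and DB, 894 for VD and DD and 1172 for the strains in DA, by construction. No filter gave 854 for A and B, 609 for VB and DB, 6075 for motor neurons and other cells and 183 for the strains in DB. All classes in 1 fit gave 1435 for transmitter, 725 for A and B and 610 for VB and DB, and at least 50 cells per sum gave 690 for VB and DB. The DESeq2 Wald test gave 189 for VA and DA, 280 for VD and DD, and 412, 378 and 280 for the strains in DA, DB and VB. Thinned cells gave 446, 365 and 177 there, with fewer genes tested. Against other neurons alone, chosen after the data were seen, motor neurons differed in 1038 genes. With a library left out, counts were 298 to 551 for A and B, 175 to 453 for VB and DB, and, in the fit of all classes, 1270 to 1282 for transmitter (1435 with all libraries), 258 to 270 for VA and DA (444) and 337 to 396 for VD and DD (527). They were 571 to 853, 418 to 783 and 128 to 531 for the strains in DA, DB and VB, and 16 to 17 for subclasses, where fewer could be tested. A lone library is assumed to vary like the other group. As shares of all cells the class differences were 6.58 (DA), 6.22 (DB), -13.3 (AS), 10.7 (VA), 14.4 (VB), -10.8 (VC), -2.46 (DD) and -22.2 (VD) percentage points, and in cells with at least 1000 UMIs 17.3 (DB), -10.1 (AS), 20.5 (VA), 36.7 (VB), -26.5 (VC), -5.29 (DD) and -48.6 (VD). Nuclear hormone receptors in place of homeobox genes gave an accuracy of 22.4%. Without the library block the count was 222 for A and B and 176 for VB and DB, and it stayed within 1.5 times for the other comparisons and for classes. The genes raised per subclass moved more, as in DA2_5 (70 to 19), AS9_10 (82 to 49) and DB2 (29 to 5). The replicate number as a block gave 679, 740 and 340 genes for the strains in DA, DB and VB. These numbers do not pair the libraries, with correlations of deviations of 0.012 in DA, -0.009 in DB and 0.078 in VB.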

Other observations

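The comparison of ventral with dorsal classes was made only after the data were seen, and the genes named here were chosen after their values were seen.

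Ventral and dorsal neurons of the A and B types shared part of their differences. Of 3264 genes tested in both, 297 were called in VA against DA and 328 in VB against DB, with 158 called in both where 29.9 would be expected by chance (odds ratio 18.7, Fisher exact p = 2.6e-92). The expected numbers and the Fisher test take genes as independent and equally likely to be called. That was not checked, so they only describe the overlap. Of these, 152 (96.2%) had the same direction, with 79 higher and 73 lower in the ventral class, among them bnc-1, nlp-58, unc-6 and lgc-36 higher and unc-129, mab-9, gbb-2 and lev-1 lower. The acr-2::GFP libraries are shared between these comparisons, but the cells are not. VD against DD shared 91 genes with VA against DA (22.4 expected; odds ratio 7.31; 59.3% in the same direction) and 77 with VB against DB (23.1 expected; odds ratio 5.64; 63.6%). The overlaps were not tested against each other, and VD against DD shares no library with VA against DA. In all 3 comparisons 41 genes were called and 27 had the same direction, with 15 higher in the ventral class, such as oig-1, exp-2, sax-3, nlp-45 and nab-1, and 12 lower, such as unc-8, mec-6, sdn-1 and unc-82.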
